A study of Mus musculus with 8 samples.

How the data were processed

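The data were Visium libraries for formalin-fixed tissue from paraffin sections 7 µm thick of mouse lung, 2 control and 6 AML-infiltrated, per the labels. Space Ranger made the deposited values on genome build mm10, per the labels; its version is not stated. The deposited matrices hold raw UMI counts per gene and spot with no normalization, tested on the files as whole numbers with a different total for each spot. Every deposited spot lay under tissue per the deposited position tables, and every spot under tissue was present. All 8 files hold the same 19465 genes with Ensembl identifiers and symbols, 11 symbols being shared by 2 identifiers. Gene positions came from GENCODE M21 of the same build, where 19451 identifiers (99.9%) were found. Image scale factors were not used.

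Groups came from the sample titles. The titles number both groups, with only 1 and 2 shared, so the numbers were not taken as pairs; the fit with the number as a block is an alternative. The library numbers in the file names fall in 2 series, which was treated as a possible batch: the fits with AML 1 to 3 and with AML 4 to 6 are given beside the pooled one. No label names a batch. Within each group no 2 sections held duplicated counts (the lowest chi-square per degree of freedom was 20.3); controls were not compared with AML sections in this.

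All tests, lists, alternatives and the rule for named genes were set before the data were examined, except where stated. UMIs were summed over the spots of each section and compared with edgeR 4.0.16 (TMM factors, filterByExpr by group, quasi-likelihood F test, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. SEs of log2 fold changes are the fold change divided by the square root of F. For genes with no control UMIs, folds are lower bounds against 3 counts over the control group; for 1 to 3 control UMIs the pooled ratio is given with its 95% counting interval.

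The 38 lists cover lung cell types, blood and immune cells, leukaemia-related genes and processes, and were written from general knowledge. Lists with at least 3 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, beside camera with an estimated correlation and fry, which tests a list against no change and not against other genes. Of 14 alveolar type 2 and 10 secretory airway genes, for example, 13 and 8 were measured.

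For the comparison within sections, the share of UMIs on the myeloid precursor list was averaged over each spot and its direct neighbours, and UMIs were summed over the top and the bottom 25% of the spots of a section. edgeR was fitted with the section as a block, the list's own members left out of the results. The control sections were divided the same way, and an interaction term tested the difference between groups. Spearman's rho between the smoothed shares of each of 36 lists and the precursor list, and Moran's I of each of 38 lists on spots thinned to 10000 UMIs, were computed within sections and compared by exact permutation tests over the 28 divisions of 8 sections, two-sided. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used.

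Named genes were, for AML against control, the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap in CPM, and up to 4 members of each list with the smallest adjusted p. For the strata they were the 10 largest rises and falls among genes that moved the same way in all 6 sections and up to 4 members of each list that passed. A set of 11 genes was always named where measured. The text gives part of the list members so selected. Gfi1b, Rhag, Epor, Ermap, Tspo2, Rhd and Alas2 in the section comparison were chosen after their values were seen.

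Alternatives were RLE size factors, no filter beyond 1 count, at least 100 counts in 2 sections, leaving out each section, the replicate block, AML 1 to 3 or 4 to 6 alone, spots with at least 1000 UMIs, leaving out spots above percentile 75 of airway or muscle list shares, sums thinned to the smallest section (15091160 UMIs), leaving out haemoglobin genes and genes over 1% of counts, DESeq2 1.42.0, and limma-trend on means over spots of counts per 10000 UMIs with a pseudocount of 0.01. For the strata they were the outer 10% of spots, single spots, the pan-leukocyte list, thinned spots, no airway or muscle spots, RLE factors and DESeq2. Airway and muscle spots were chosen by the secretory, ciliated, smooth muscle and cardiac lists, at a percentile pooled over sections. Leaving them out kept 47.9% and 36.5% of the spots in the controls and 51.3% to 85.9% in AML sections. Leaving out airway and muscle spots in the interaction test was added after seeing the data. Other divisions of the sections, and swaps of the strata within sections, were fitted too.

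The tests were tried on simulated data with 200 changed genes. In 1 version dispersions were scattered from gene to gene by the prior degrees of freedom of the quasi-likelihood fit. This scatter was not shown to equal that of the data. With it the section comparison recovered 42% of 4-fold rises, 60% of 4-fold falls, 0% of 2-fold rises and 10% of 2-fold falls. It tested 15100 genes, with 2 false calls. With 1 control and 6 AML sections it recovered 0% at each fold size. These simulations were set up after a first version, with dispersions on the trend, had recovered 94%, 92%, 44% and 30% with 2 controls, and 78%, 68%, 12% and 6% with 1 control. The comparison of strata recovered 98% of 4-fold rises, 88% of 4-fold falls, 66% of 2-fold rises and 70% of 2-fold falls among 13642 genes with scattered dispersions, with 8 false calls. A list with every member doubled was called in both lists tried, with 0 others called. Genes were simulated independently of each other, so this does not show how often lists of correlated genes are called falsely.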

Results

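Spatial gene expression was measured on 8 paraffin sections of mouse lung, 2 from normal lungs (control 1 and 2) and 6 from lungs infiltrated by acute myeloid leukaemia, AML (AML 1 to 6). The assay, Visium for formalin-fixed tissue, captures gene-specific probes on a grid of barcoded spots, and its unit is the unique molecular identifier (UMI) counted per gene and spot. The section was the replicate throughout. The labels do not say whether the sections came from separate mice, so the p-values of single genes below measure spread between sections. The camera p-values of lists set member genes against other genes. Their size rests on the correlation assumed between genes, and they do not measure spread between sections.

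Sections held 912 and 938 spots in the controls and 1279, 581, 474, 1839, 2208 and 1794 in AML 1 to 6. Their totals were 30341351 and 30961680 UMIs in the controls and 49985268, 26162203, 15091160, 100639882, 87098873 and 44885999 in AML 1 to 6. The median UMIs per spot were 31810.5 ± 187 (SD, n = 2) in control and 38621.5 ± 10593 (SD, n = 6) in AML sections (exact permutation test, two-sided, p = 0.571). The median number of genes per spot was 8053 ± 118 and 8714 ± 782 in the same groups (exact permutation p = 0.286), and the number of spots was 925 ± 18.4 and 1362.5 ± 712 (exact permutation p = 0.500). With 2 sections against 6, the smallest p such a test can give is 0.0714, so it cannot reach 0.05. The 3 p-values adjusted together were all 0.571.

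The first comparison asked which genes differ between the lungs infiltrated by AML and normal lungs. Counts were summed over all spots of a section and tested with edgeR. Of 15213 genes tested, 3195 were higher and 2029 lower in AML sections at an adjusted p under 0.05, and 7364 had an unadjusted p under 0.05. The 4252 genes with too few counts to test held 0.0228% of the UMIs. Among the genes tested, all 6 AML sections lay above both controls for 3987 genes and below both for 3851, where chance gives 7.14% of genes in all; 3079 and 2016 of the genes past the threshold were among them. The count depended on having both controls. Without control 1, 13 genes passed, and without control 2, 3 genes passed (Hbb-bs, Camp and Ctsg), in a fit that takes the lone control to vary like the AML sections. All 5224 genes kept their direction in both of these fits. This is weak support, since the genes were chosen on the same sections. For the 3079 and 2016 whose groups did not overlap, leaving out 1 control could hardly reverse the direction. The same holds for the directions of single genes without a control given below. Without AML 3, 2088 genes were higher; without AML 5, 3358 genes passed, 1027 of them lower; without AML 6, 3426 were lower. The file names number the libraries of the controls and AML 1 to 3 in 1 series and those of AML 4 to 6 in another. With AML 1 to 3 and both controls, 4084 genes were higher and 3292 lower, and 4954 of the 5224 genes passed again. With AML 4 to 6 and both controls, 1225 were higher and 1126 lower, and 2013 of the 5224 passed again.

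**Figure D1:**
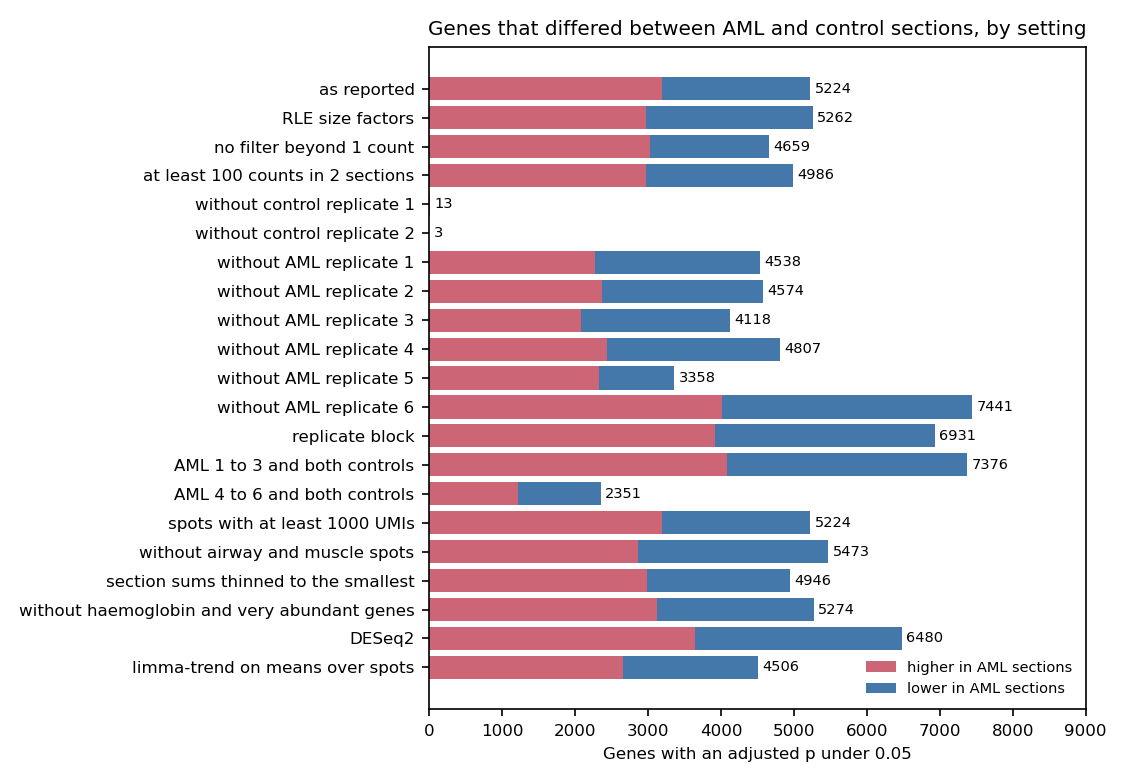
Number of genes with an adjusted p under 0.05 between AML and control sections (x axis, genes) as reported and under each alternative (y axis), split by direction. The bars show 5224 genes as reported, 13 and 3 genes when either control is left out, and between 2351 and 7441 genes under the other alternatives.

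The 10 genes with the largest fitted log2 rise among those past the threshold whose groups did not overlap had between 0 and 3 UMIs in the 2 controls together. With so few control UMIs, their rank over other genes with large rises is uncertain. Trap1a (chromosome X, 139333683 to 139338169, mm10) had 1 UMI in the controls and 110.6 ± 89.2 CPM (the gene's UMIs scaled to the section's total; SD, n = 6) in AML sections, a ratio of pooled counts of 9549 with a 95% counting interval of 1714 to 3.77e+05. Car1 had 2 control UMIs and a ratio of 6621 (1833 to 5.47e+04), and Kel had 3 and a ratio of 1217 (417 to 5904). The other 7 genes had no control UMIs, and their folds are lower bounds against 3 counts over the control group: Pet2 was at least 229-fold higher, Hoxc9 219-fold, Prss50 172-fold, Sva 150-fold, Prss42 125-fold, Ctsg 89.5-fold and Elane 80.8-fold. Intervals and floors cover counting error only. Hbb-bs (chromosome 7, 103826534 to 103828096) fell the furthest, with a log2 fold change of −3.87 ± 0.31 (SE), from 4992 ± 16.9 CPM (SD, n = 2) to 332 ± 102 CPM (SD, n = 6; adjusted p = 0.000930). The other large falls, in log2, were Ccl20 (−3.10), Hbb-bt (−2.99), Hba-a2 (−2.91), Chrdl2 (−2.88), Hpcal4 (−2.86), Grem1 (−2.79), Fga (−2.76), Cilp (−2.74) and Rptn (−2.68). Each of these 20 genes passed without any 1 of the AML sections. Without control 1, 18 of the 20 no longer passed (adjusted p of 0.05 or more), and without control 2, 18 again; Hbb-bs and Ctsg passed in both. Grem1 and Pet2 did not pass with AML 4 to 6 alone, nor Grem1 in limma.

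Fixed gene lists were tested for whether their members moved differently from all other genes (camera, preset correlation 0.01). Of 38 lists, 15 passed at an adjusted p under 0.05, 5 rising and 10 falling, and 17 had an unadjusted p under 0.05. With an estimated correlation between genes 0 lists passed in camera: the lowest adjusted p over the 38 lists was 0.493, and 2 lists had an unadjusted p under 0.05. Against no change, which is another question than camera's, fry called 12 of the 38 lists, 9 of the 15 among them. The list calls below therefore rest on the preset correlation. Proliferation genes had the smallest p (adjusted p = 1.01e-19; adjusted p = 0.575 with an estimated correlation): 19 of 20 members were higher, and 19 adjusted over the list alone. All 10 members of the list Myc and ribosome biogenesis were higher, and 10 adjusted over the list alone (adjusted p = 3.42e-09; adjusted p = 0.575 with an estimated correlation). In the myeloid precursor list 8 of 10 members were higher, and 8 adjusted over the list alone (adjusted p = 1.84e-08; adjusted p = 0.493 with an estimated correlation). Its median log2 fold change was 3.76, also with the 3 members that had no control UMIs set to their lower bounds. Among neutrophil genes 5 of 12 were higher, and 7 adjusted over the list alone (adjusted p = 3.74e-05; adjusted p = 0.575 with an estimated correlation). Among pan-leukocyte genes 4 of 11 were higher, and 6 adjusted over the list alone (adjusted p = 0.000835; adjusted p = 0.575 with an estimated correlation).

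Mki67 rose from 15.5 ± 0.175 CPM (SD, n = 2) to 229 ± 81.4 CPM (SD, n = 6), a log2 fold change of 3.93 ± 0.45 (SE; adjusted p = 0.00204). Myc rose from 15.1 ± 0.377 to 175 ± 59.8 CPM and Myb from 59.2 ± 3.08 to 438 ± 160 CPM. The log2 fold changes of Cdk1, Birc5, Nop56 and Npm1 were 3.49, 3.72, 2.45 and 1.92. Of the neutrophil list, Camp rose by 5.90, Ngp by 5.80, S100a8 by 2.68 and S100a9 by 2.77 on the log2 scale. Mpo had 1 control UMI and a pooled ratio of 180 (95% counting interval 32.3 to 7132). Spn rose by 2.78 and Arhgdib by 2.19 on the log2 scale, while the leukocyte gene Ptprc did not pass (0.95 ± 0.41, adjusted p = 0.0974, higher than both controls in 5 of 6 AML sections; it passed in DESeq2). Of the 14 genes in this paragraph that passed, all did so without any 1 AML section, 11 no longer passed without control 1 and 13 without control 2; no direction changed.

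The erythroid list split. It did not pass (adjusted p = 0.138), since 6 of its 9 members were higher and 3 lower, and the same counts were found adjusted over the list alone. The regulators Gata1 (chromosome X, 7959260 to 7978071) and Klf1 rose from 1.14 ± 0.214 to 178 ± 72.9 CPM and from 0.162 ± 0.136 to 33.4 ± 13.5 CPM, log2 fold changes of 7.32 ± 0.65 and 7.68 ± 0.80 (SE). A set of further erythroid genes, chosen after the values were seen, was also higher in all 6 AML sections: Gfi1b, Rhag, Epor, Ermap and Tspo2 rose by 8.06, 10.18, 2.93, 7.85 and 8.25 on the log2 scale, and Rhd, with 3 control UMIs, had a pooled ratio of 875 (299 to 4245). Alas2 fell by 2.10 on the log2 scale, like the haemoglobin genes. Without control 1, 7 of these 9 genes no longer passed, and without control 2 all 9 calls were lost; all kept their direction.

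**Figure D2:**
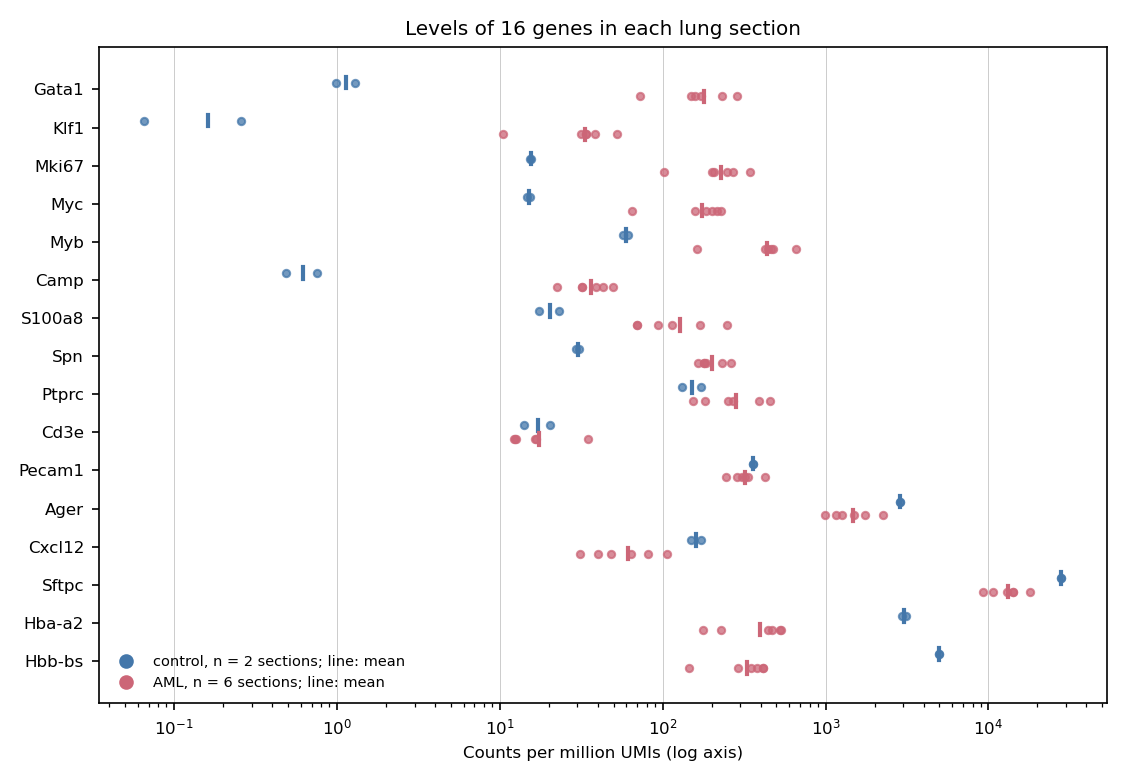
Levels of 16 genes in CPM (x axis, log scale) in each of the 2 control and 6 AML sections; points are sections and lines are group means. Gata1 and Klf1 rose from 1.14 and 0.162 to 178 and 33.4, while Hbb-bs fell from 4992 to 332.

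Lists of resident lung cells fell relative to the other RNA of a section. For these lists and their genes, niche factors included, dilution by RNA of infiltrating cells was not told apart from loss of cells or of expression. All 12 ciliated airway genes were lower, and 12 adjusted over the list alone (adjusted p = 5.25e-07; adjusted p = 0.575 with an estimated correlation), as were 11 of 13 alveolar type 2 genes, and 13 adjusted over the list alone (adjusted p = 7.56e-07; adjusted p = 0.575 with an estimated correlation). Among fibroblast genes 9 of 13 were lower, and 12 adjusted over the list alone (adjusted p = 1.74e-05; adjusted p = 0.575 with an estimated correlation), and among alveolar type 1 genes 7 of 10 in both counts (adjusted p = 0.000405; adjusted p = 0.575 with an estimated correlation). In AML 6 the fibroblast genes held 4635 CPM, between the controls' 5033 and 4470, against 2190 to 2777 in AML 1 to 5. Smooth muscle and pericyte genes were lower for 4 of 12, and for 7 adjusted over the list alone (adjusted p = 0.00157; adjusted p = 0.594 with an estimated correlation). Haematopoietic niche factors were lower for 4 of 11, and for 5 adjusted over the list alone (adjusted p = 0.00224; adjusted p = 0.575 with an estimated correlation). Secretory airway genes were lower for 4 of 8 in both counts (adjusted p = 0.0109; adjusted p = 0.575 with an estimated correlation), with a median log2 fold change of −1.22 but a mean of 0.26. Without airway and muscle spots the ciliated and secretory lists did not pass (adjusted p = 0.224 and 0.452). Those spots were chosen by the shares of these same lists, so this loss was partly built in. The other 3 lists were near the threshold: endothelium (adjusted p = 0.0277; adjusted p = 0.673 with an estimated correlation), with 0 of 15 members past the threshold in either count in edgeR (3 at an unadjusted p under 0.05, 2 in DESeq2 and 0 in limma), mesothelium (adjusted p = 0.0369; adjusted p = 0.594 with an estimated correlation), with 1 of 5 lower and none adjusted over the list alone, and matrix and remodelling (adjusted p = 0.0394; adjusted p = 0.603 with an estimated correlation), with 1 higher and 4 lower of 12 in both counts. These 3 calls ended when single sections were left out. The endothelium list gave 0.0668 without AML 1. The mesothelium list gave 0.0566 without control 1 and 0.0730, 0.0665 and 0.0516 without AML 1, 4 and 6. The matrix list gave 0.0976 without control 2 and 0.0827, 0.0611, 0.0640 and 0.0665 without AML 1, 2, 3 and 4. With AML 4 to 6 alone the endothelium and matrix lists gave 0.0765 and 0.202, and the mesothelium list gave 0.0616 with at least 100 counts and 0.0511 with thinned sums.

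Sftpc (chromosome 14, 70520949 to 70524081), the surfactant gene with the most UMIs, fell from 27890 ± 104 CPM (SD, n = 2) to 13252 ± 3082 CPM (SD, n = 6), a log2 fold change of −1.03 ± 0.27 (SE; adjusted p = 0.02095). Hc, Lamp3 and Slc34a2 changed by −1.37, −1.04 and −1.06 on the log2 scale. Ager fell from 2862 ± 20.6 to 1481 ± 459 CPM, and Aqp5 and Pdpn changed by −1.18 and −1.31. The airway genes Scgb3a2, Cyp2f2, Dnah5 and Rsph1 changed by −1.69, −1.23, −1.35 and −1.25, and Col1a1, Dcn, Tagln and Lmod1 by −1.84, −1.15, −1.57 and −1.25. The niche factor Cxcl12 (chromosome 6, 117168535 to 117181367) fell from 161 ± 16.7 to 61.7 ± 28.3 CPM, a log2 fold change of −1.35 ± 0.37 (SE; adjusted p = 0.0251), and Vcam1, Il7 and Jag1 changed by −0.94, −1.43 and −0.55. Pecam1 was not shown to differ (−0.13 ± 0.19, adjusted p = 0.623, lower than both controls in 5 of 6 AML sections). Of the 19 genes in this paragraph that passed, none did without control 1 or without control 2, and all kept their direction. Vcam1 also no longer passed without AML 3 or AML 4, and Ager, Cyp2f2, Jag1 and Vcam1 without AML 5. With AML 4 to 6 alone, 10 of the 19, Sftpc among them, no longer passed, and with AML 1 to 3 alone Cyp2f2 did not. Without airway and muscle spots, chosen in part by the lists that hold the 4 airway genes, all 4 and Jag1 no longer passed. In limma Sftpc, Cyp2f2 and Dcn did not pass, nor did Vcam1 with thinned sums.

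**Figure D3:**
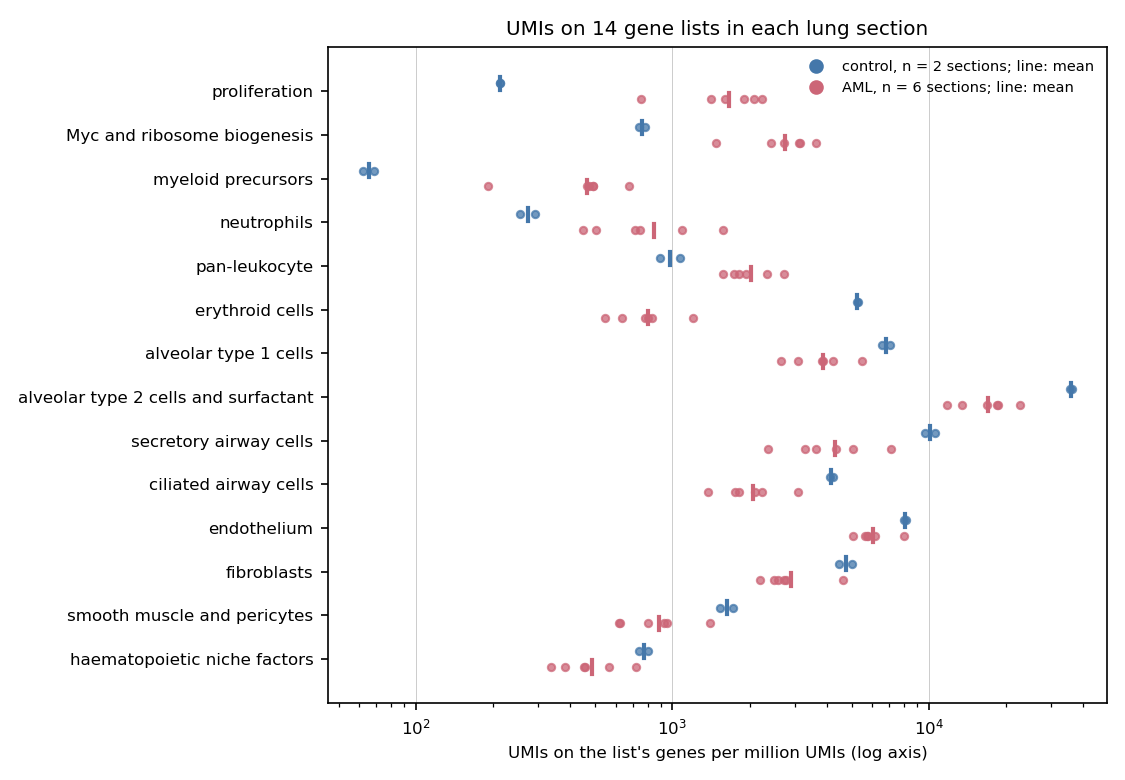
Summed CPM of the genes of 14 lists (x axis, log scale) in each of the 2 control and 6 AML sections; points are sections and lines are group means. The proliferation list held 213 CPM in control and 1667 in AML sections, and the alveolar type 2 list held 35789.5 and 16988.

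The remaining 22 lists, besides the erythroid list, did not pass, with adjusted p between 0.106 and 0.854. They were aerocytes, large-vessel and lymphatic endothelium, cardiac muscle, alveolar and interstitial macrophages, monocytes, stem and progenitor regulators, megakaryocytes and platelets, T cells, natural killer cells, B cells, plasma cells, dendritic cells, mast cells and basophils, type I interferon response, antigen presentation, inflammatory cytokines, immune checkpoints, hypoxia, lipid synthesis, and immediate early genes. Of the 81 members of the T cell, natural killer, B cell, dendritic cell, interferon, antigen presentation and immediate early lists, 0 passed in edgeR, over all genes or adjusted over the list alone; 2 had an unadjusted p under 0.05, 3 passed in DESeq2 and 1 in limma. Cd3e (17.2 ± 4.54 CPM in control, 17.5 ± 8.63 CPM in AML sections) had a log2 fold change of 0.08 ± 0.42, Irf7 of 1.42 ± 0.67 and H2-Aa of −0.89 ± 0.42 (SE). The sign of Cd3e was negative without control 2 (−0.17) and without AML 6 (−0.26). Among single members that did pass, Ms4a2 and Cpa3 rose by 4.55 and 3.25, Il1b by 1.60 and Tgfb1 by 0.87 on the log2 scale. Il10, with 2 control UMIs, had a pooled ratio of 154 (42.5 to 1269), and Cxcl1, Icam1, Vegfa and Scd1 changed by −2.23, −0.84, −1.47 and −1.54. Irf7 passed in DESeq2, and H2-Aa without AML 6 (−1.23) and with AML 1 to 3 alone (−1.26). The 9 genes that passed did so without any 1 AML section and did not pass without control 1 or without control 2. With AML 4 to 6 alone, Cpa3, Cxcl1, Icam1, Il1b, Scd1 and Vegfa no longer passed. Hoxa9 had too few counts to be tested, and Scgb1a1 was not analysed here.

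The second comparison asked what differs, within AML lungs, between places with more and with less signal of immature myeloid cells. Each spot was ranked by its share of UMIs on the myeloid precursor list, taken as a guide to leukaemia cells and averaged with its neighbours on the grid, and the top 25% of the spots of a section were compared with the bottom 25%, with the section as a block. These precursor-high and precursor-low spots held between 284 and 786 and between 102 and 537 CPM on the list in AML sections. Myb alone gave between 84.8% and 97.4% of the list's UMIs in each of the 8 sections. The strata differed in depth, with 43049 and 33952 median UMIs per spot in AML 1, for example. Of 13737 genes tested in edgeR, 3166 were higher and 2644 lower in precursor-high spots, and 7259 had an unadjusted p under 0.05. Of the 5810 genes, 4423 moved the same way in all 6 sections. With every spot thinned to 10000 UMIs, 1145 were higher and 908 lower, and 1986 of the 5810 passed again. Without AML 1, 1614 were lower; without AML 4, 3833 passed, 1538 of them lower; and without AML 5, 3732 passed, 1531 of them lower.

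The 10 largest rises in precursor-high spots among genes that moved the same way in all 6 sections were Ighg2b (log2 fold change 1.60 ± 0.52, SE), Cd5l (1.16 ± 0.23), Cxcl10 (1.005 ± 0.15), Ccl4 (0.95 ± 0.19), Slc9b1 (0.84), Itgad (0.83), Tex16 (0.83), Hcn3 (0.82), Pou4f1 (0.81) and Slc17a4 (0.80). Their mean levels in precursor-high spots were low, at most the 24.0 CPM of Cd5l. The 10 largest falls were genes of striated muscle: Actn2 (−3.46 ± 0.23), Trdn (−3.46), Ckm (−3.44), Myoz2 (−3.38), Smpx (−3.38), Pln (−3.32), Myl7 (−3.28), Mybphl (−3.27), Mybpc3 (−3.14) and Pgam2 (−3.11). Actn2 stood at 3.84 ± 4.34 CPM in precursor-high and 47.5 ± 60.8 CPM in precursor-low spots (SD, n = 6). Itgad and Slc17a4 did not pass without AML 1, Ighg2b and Itgad without AML 3, Ighg2b, Itgad and Slc17a4 without AML 4, and Ighg2b and Slc17a4 without AML 5. With airway and muscle spots left out, the difference of Pln was 0.06, and Actn2, Myl7 and Tex16 did not pass. With spots thinned to 10000 UMIs, Ccl4, Cxcl10, Itgad and Pou4f1 did not pass, and with the share of the spot alone, Cxcl10, Hcn3, Itgad, Slc17a4 and Tex16 did not. Ccl4 and Tex16 did not pass with the outer 10% of spots, Hcn3 and Ighg2b with the pan-leukocyte list, and Hcn3 and Slc17a4 in DESeq2. Some alternatives left several of the 20 genes untested.

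Of 37 lists tested on the same spots, 13 passed with the preset correlation, 4 rising and 9 falling, and 19 had an unadjusted p under 0.05. Against no change, fry called 24 of the 37 lists, 11 of the 13 among them. Only smooth muscle and pericytes passed with an estimated correlation (adjusted p = 0.0271 with an estimated correlation), where 9 of 12 members were lower in both counts. All 19 proliferation genes (adjusted p = 7.01e-19; adjusted p = 0.182 with an estimated correlation), all 10 genes of the list Myc and ribosome biogenesis (adjusted p = 1.01e-14; adjusted p = 0.162 with an estimated correlation) and all 11 pan-leukocyte genes (adjusted p = 1.23e-07; adjusted p = 0.257 with an estimated correlation) were higher in precursor-high spots, in both counts. So were 6 of 9 erythroid genes, in both counts (adjusted p = 0.000778; adjusted p = 0.366 with an estimated correlation). Lower were 6 of 7 cardiac muscle genes in both counts (adjusted p = 1.51e-15; adjusted p = 0.182 with an estimated correlation), 11 of 13 fibroblast genes, and 12 adjusted over the list alone (adjusted p = 5.07e-14; adjusted p = 0.0643 with an estimated correlation), all 13 alveolar type 2 genes in both counts (adjusted p = 2.61e-05; adjusted p = 0.366 with an estimated correlation), and 5 of 7 interstitial macrophage genes in both counts (adjusted p = 0.000261; adjusted p = 0.182 with an estimated correlation). In the matrix list 8 were lower and 1 higher of 12 in both counts (adjusted p = 0.00635; adjusted p = 0.366 with an estimated correlation). In the niche factor list 6 were lower and 1 higher of 11, and 7 and 1 adjusted over the list alone (adjusted p = 0.0465; adjusted p = 0.257 with an estimated correlation). Ciliated genes were lower for 3 of 12, and for 9 adjusted over the list alone (adjusted p = 0.0105; adjusted p = 0.581 with an estimated correlation), and secretory genes for 3 of 6, and for 5 adjusted over the list alone (adjusted p = 0.0262; adjusted p = 0.581 with an estimated correlation). With airway and muscle spots left out, the ciliated list rose without passing (adjusted p = 0.291), and the secretory and cardiac lists did not pass (adjusted p = 0.944 and 0.502). These lists helped to choose the spots left out, so their loss was partly built in. Falls in precursor-high spots are relative to the other RNA there, so dilution by RNA of infiltrating cells was not told apart. The niche factor list did not pass without AML 4 (adjusted p = 0.0544) or without AML 6 (adjusted p = 0.131), nor the matrix list without AML 6 (adjusted p = 0.116). The niche factor list did not pass with thinned spots either (adjusted p = 0.128), or with the outer 10% of spots (adjusted p = 0.0505). With spots ranked by the pan-leukocyte list, 5 lists no longer passed: alveolar type 2 (adjusted p = 0.520), cardiac muscle (0.287), interstitial macrophages (0.379), niche factors (0.453) and matrix (0.721).

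**Figure D4:**
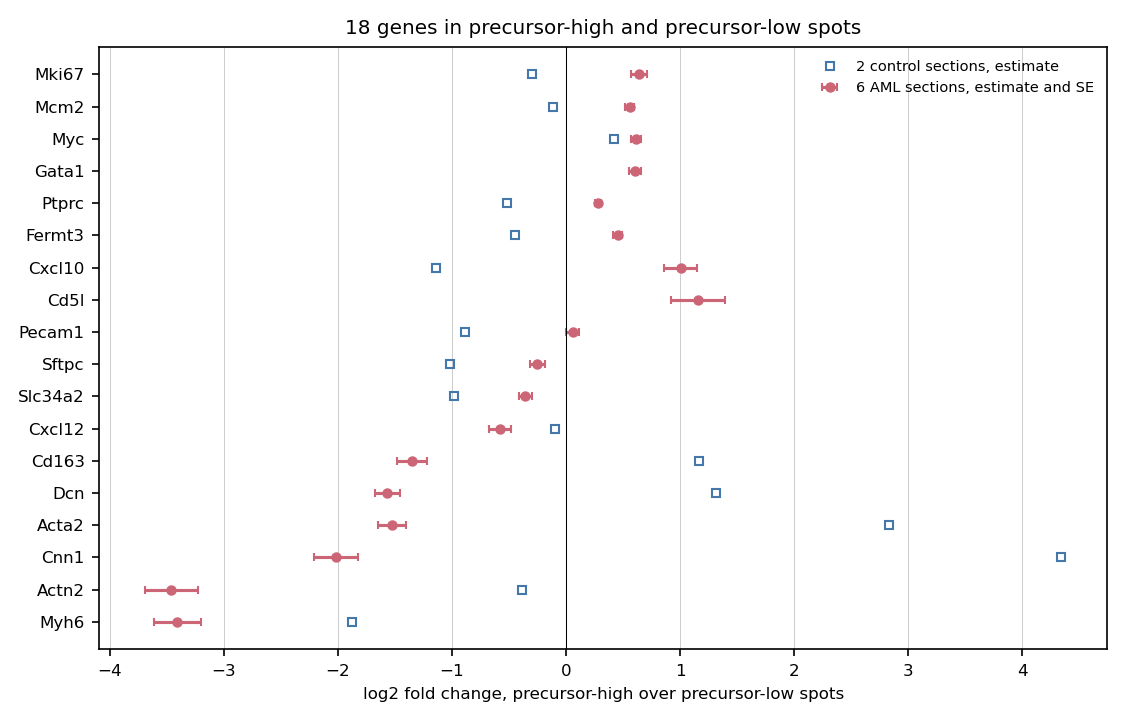
Log2 fold change between precursor-high and precursor-low spots (x axis) of 18 genes, with its SE, in 6 AML sections, and the estimate in 2 control sections as background. Cnn1 lay at −2.02 in AML and 4.34 in control sections, and Mki67 at 0.64 and −0.29; Gata1 and Cd5l had too few counts in the controls.

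Mki67 stood at 270 ± 92.8 CPM in precursor-high and 176 ± 74.7 CPM in precursor-low spots (SD, n = 6), a log2 fold change of 0.64 ± 0.07 (SE; adjusted p = 0.000444, higher in 6 of 6 sections). The log2 fold changes of Mcm2, Myc, Gata1, Rhag and Klf1 were 0.56, 0.61, 0.61, 0.59 and 0.59, and those of Fermt3, Was and Ptprc were 0.45, 0.47 and 0.28. The stromal genes Dcn, Col3a1, Acta2 and Cnn1 changed by −1.56, −0.89, −1.52 and −2.02, the cardiac gene Myh6 by −3.41, and the macrophage genes Cd163 and C1qa by −1.35 and −0.41. Of the alveolar genes, Sftpa1, Slc34a2 and Sftpc changed by −0.59, −0.36 and −0.25, and Ager did not pass (−0.11 ± 0.06, lower in 4 of 6 sections). The airway genes Muc5b, Scgb3a2 and Foxj1 changed by −2.28, −1.85 and −1.49, each in 5 of 6 sections. Cxcl12 was lower in all 6 sections (−0.58 ± 0.10, adjusted p = 0.00270), while Vcam1, Pecam1 and Cd3e did not pass (−0.16, 0.06 and 0.05). Foxj1 and Scgb3a2 no longer passed when any 1 of AML 1 to 5 was left out, Muc5b when AML 1, 2, 4 or 5 was, and Sftpc when AML 3, 4 or 5 was. With airway and muscle spots left out, Acta2, Cnn1, Myh6 and Cd163 no longer passed, and Scgb3a2 (0.17), Foxj1 (0.43), Pecam1 (−0.13) and Cd3e (−0.11) changed sign. With the spots ranked by the pan-leukocyte list instead, Sftpc, Ager and Vcam1 changed sign (0.0067, 0.09 and 0.09), Slc34a2 and Myh6 no longer passed, and Pecam1 (0.38) and Cd3e (0.64) did. With thinned spots Muc5b, Scgb3a2 and Sftpc no longer passed, and with the share of the spot alone Foxj1 did not. Vcam1 passed with the share of the spot alone (−0.44) and with the outer 10% of spots (−0.39), and Ager without airway and muscle spots (−0.31).

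The same division of the control sections gave the background. Their precursor-high spots held 177 and 169 CPM on the list and their precursor-low spots 8.82 and 8.15, and 7761 of 13656 genes and 18 of 36 lists differed between them. Ciliated and secretory airway genes were higher there, with median log2 fold changes of 4.22 and 4.75 (adjusted p = 2.55e-16 and 1.39e-08; adjusted p = 0.712 with an estimated correlation for both). A direct test of whether the difference between the strata differs between AML and control sections called 7224 of 13542 genes, with 4259 more positive and 2965 more negative in AML sections. With airway and muscle spots left out, an alternative chosen after seeing the data, it called 127 genes, 25 and 102 in the same directions, 59 of them shared with the 7224. That removal took a larger part of the control than of the AML spots, so the lower count does not test a cause. With those spots kept, leaving out any 1 section gave between 4849 and 7828 genes.

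Across spots, Spearman's rho of each of 36 lists with the precursor list was computed within each section; spots are not independent replicates, so the groups were compared over sections. For 29 lists all AML sections lay on 1 side of both controls, 22 higher and 7 lower, where chance gives 7.14% of lists (exact permutation test, smallest p = 0.0714, the smallest this design allows; adjusted over 36 lists 0.0887). Proliferation had a rho of −0.037 ± 0.023 in control and 0.646 ± 0.076 in AML sections (SD, n = 2 and 6). The pan-leukocyte list had −0.322 ± 0.052 and 0.478 ± 0.081, smooth muscle 0.576 ± 0.077 and −0.337 ± 0.071, and secretory airway 0.854 ± 0.012 and −0.211 ± 0.161. Fibroblasts (−0.510 ± 0.116 and −0.418 ± 0.114) and niche factors (−0.327 ± 0.087 and −0.234 ± 0.115) were negative in all 8 sections and did not separate the groups.

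**Figure D5:**
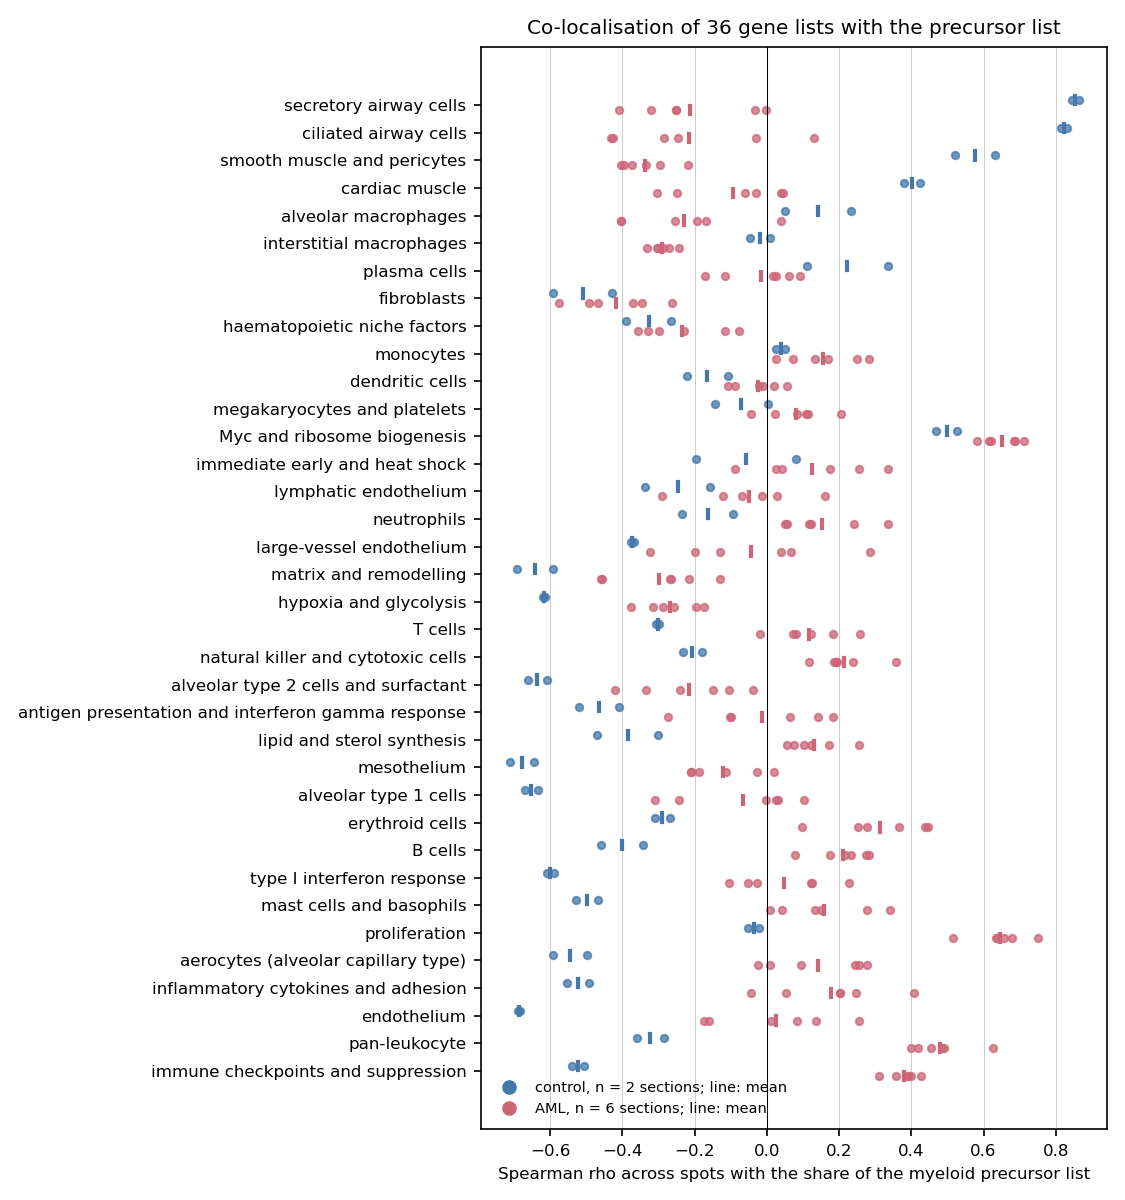
Spearman's rho across spots between the share of each of 36 lists and that of the myeloid precursor list (x axis), in each of the 2 control and 6 AML sections; points are sections and lines are group means. Proliferation lies at −0.037 in control and 0.646 in AML sections on average, and secretory airway genes at 0.854 and −0.211.

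Moran's I, the autocorrelation of a list's share over neighbouring spots, was computed on spots thinned to 10000 UMIs. It separated the groups for 20 of 38 lists, 3 higher and 17 lower in AML sections, where chance gives 7.14% (exact permutation test, smallest p = 0.0714; adjusted over 38 lists 0.136). The 3 that were higher were proliferation (0.036 ± 0.039 in control, 0.248 ± 0.028 in AML sections), Myc and ribosome biogenesis (0.052 ± 0.032 and 0.213 ± 0.033) and stem and progenitor regulators (0.029 ± 0.010 and 0.150 ± 0.031; SD, n = 2 and 6). The myeloid precursor list itself fell from 0.337 ± 0.009 to 0.083 ± 0.026, endothelium from 0.654 ± 0.042 to 0.379 ± 0.089, and the erythroid list from 0.366 ± 0.116 to 0.089 ± 0.020. With spots not thinned, 17 lists separated the groups. Thinning set the total per spot and not the UMIs on a list, and Moran's I falls with counting noise. The 3 higher lists also held more CPM in AML than in control sections (1667 and 213, 2751 and 761, 1969 and 1310). Endothelium (6060 and 8053) and the erythroid list (800 and 5269) held less. For these lists, level and spatial pattern cannot be told apart. The precursor list fell although it held more (464 and 65.4). Across spots its rho with the ciliated list was 0.814 and 0.831 in the controls and −0.431 to 0.131 in AML sections. Its fall may therefore compare UMIs of different cells in the 2 groups, which was not tested.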

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

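Of the tests in this part, the one of spot depth, the thinning of Myb and the fit of the difference without airway and muscle spots were chosen after the result was seen. Among 191 groups of 6 AML values, 17 had 1 section far from the other 5 (its gap to the nearest exceeded 0.625 of the range), where about 9.55 would by chance.

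AML 6 lay above the other 5 AML sections by this measure in the summed CPM of 7 lists: 2674 on cardiac muscle genes (next highest 753), 8025 on endothelium, 4635 on fibroblasts, 3561 on immediate early and heat shock genes, 3401 on matrix genes, 187 on platelet genes and 174 on natural killer genes. Its endothelium, fibroblast and matrix values lay between those of the controls (7979 and 8126, 5033 and 4470, 3165 and 3609). The cardiac, immediate early, platelet and natural killer values lay above both controls. AML 6 also held the least of the AML sections on the precursor (192, others 465 to 678) and proliferation lists (754, others 1411 to 2245), which this measure did not flag. It did so too in the CPM of the single genes Cd3e (34.6), Col1a1 (200.1), H2-Aa (547) and Scd1 (147), and in Moran's I of endothelium (0.554), immediate early genes (0.719) and interferon response (0.329). Among AML sections, AML 1 lay below the others in Moran's I of plasma cell genes (0.0138) and above them in Mpo (6.76 CPM), and AML 2 above them in Ms4a2 (17.0 CPM). The Wilson 95% intervals of the shares and CPM reached at most 10.7% to either side.

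The difference between precursor-high and precursor-low spots itself differed between AML and control sections for 7224 genes, by an interaction test. For 11 lists the rho with the precursor list had 1 sign in all 6 AML sections and the opposite sign in both controls: B cells, erythroid cells, immune checkpoints, lipid synthesis, mast cells, natural killer cells, neutrophils, pan-leukocyte, proliferation, secretory airway and smooth muscle. The opposite signs were not tested as such.

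The precursor-high spots of the control sections were airway spots, with a rho of 0.814 and 0.831 between the precursor and ciliated lists. More UMIs per airway spot are argued against as the cause, since with every spot thinned to 10000 UMIs the lower of the 2 values was 0.729. A candidate explanation is Myb, which in these normal lungs lies outside leukaemia cells and gave 89.8% and 91.4% of the list's UMIs. The precursor list without Myb had a rho of at most 0.161 with the ciliated list, while Myb thinned to the same 211 and 167 UMIs had a median rho of 0.670 and 0.669 over 20 draws. Without airway and muscle spots the difference between groups was called for 127 genes. That count does not decide the cause, since a larger part of the control than of the AML spots was removed. Which cells carry Myb was not tested, and a biological difference between the strata of the 2 groups stays open. In AML 6 the rho of the precursor list with the ciliated list was positive too (0.131, against −0.431 to −0.031 in AML 1 to 5). Its strata may therefore hold some airway signal, although its rho with the secretory list was −0.032.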

How the results depend on the processing

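Of the alternatives in this part, only the fit of the difference between groups without airway and muscle spots was chosen after the result was seen.

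Leaving out 1 section gave 3 to 7441 genes between AML and control sections, 2 to 4015 higher and 1 to 3426 lower. The lowest values came from leaving out a control (13 and 3 genes), in fits that take the lone control to vary like the AML sections. In simulations with 1 control, 0% of 4-fold rises were recovered with dispersions scattered from gene to gene and 78% with dispersions on the trend, so the smaller number of controls alone was not shown to be the cause. With AML 1 to 3, 3292 genes were lower; with AML 4 to 6, 2351 passed, 1225 higher and 1126 lower, and the cause was not tested. RLE factors gave 5262 genes, no low-count filter 4659, at least 100 counts 4986, no airway or muscle spots 5473, thinned sums 4946, no haemoglobin or very abundant genes 5274, DESeq2 6480 and limma-trend 4506. The numbers in the titles taken as a block gave 6931 genes (3913 higher, 3018 lower), with Ptprc and H2-Aa passing and Fga not; the control 1 minus 2 and AML 1 minus 2 differences correlated across genes at 0.153. No spot had fewer than 1000 UMIs, so that minimum tested nothing. Without airway and muscle spots the median log2 fold change over all genes shifted by −0.09; fits without 1 section were not compared in this. Between 12 and 21 lists passed.

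For precursor-high against precursor-low spots, leaving out 1 section gave 3732 to 7515 genes, 2201 to 4024 higher and 1531 to 3491 lower, and lists numbered 12 to 15 in all alternatives. The pan-leukocyte list gave 4802 higher genes (the cause was not tested), and thinned spots 2053 genes, 1145 higher and 908 lower, with fewer UMIs tested. The difference between groups was called for 127 genes (25 and 102) without airway and muscle spots; the cause was not tested. Lists separated by rho numbered 29 to 35, and by Moran's I 17 to 29.

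Of 76 named genes between sections, 4 kept their direction and side of the threshold under every alternative, and 48 under every alternative that keeps both controls; of 47 in the strata, 23 did, as did 10 of 15 and 6 of 13 lists. Without 1 section, Cd3e between sections ranged from −0.26 (without AML 6) to 0.34 (without control 1), with −0.17 without control 2; it was −0.46 with the block, −0.33 with AML 1 to 3, −0.012 without airway and muscle spots and −0.071 in limma-trend. In the strata, the pan-leukocyte list reversed Sftpc (0.0067), Ager (0.094) and Vcam1 (0.095), and the share of the spot alone reversed Cd3e (−0.040). Leaving out airway and muscle spots reversed Pecam1 (−0.13), Cd3e (−0.11), Pln (0.065), Scgb3a2 (0.17), Foxj1 (0.43) and the ciliated list (adjusted p = 0.291). The cause of these reversals was not tested. Depth limits genes with few UMIs: 4252 genes were not tested, and folds of genes with 0 control UMIs are bounds.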

Other observations

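Of the tests in this part, those of late erythroid genes, of the library series, of dilution and of whole blood were chosen after the result was seen.

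Early erythroid genes rose while globin genes fell in AML sections: 9 early genes (Gata1, Klf1, Gfi1b, Rhag, Epor, Kel, Ermap, Tspo2 and Rhd) held 7.25 and 8.59 CPM in the controls and 332 to 1589 in AML sections, and 4 late genes (Hbb-bs, Hbb-bt, Hba-a2 and Alas2) held 8405 and 8224 in the controls and 340 to 992 in AML sections. Maturing red cell precursors of the host stay open as the source: the late genes had a median log2 fold change of −2.95, but that fall is part of the pattern itself, and a loss of circulating red cells would hide late genes brought in by precursors. A difference between the 2 series of library numbers is argued against, since all 9 early genes passed with AML 1 to 3 and both controls, which share a series. A hypothesis, found and tested on the same sections, is that the proliferating infiltrating cells may carry the early genes: rho across spots between the early genes and proliferation was 0.821 to 0.870 in AML sections (median 0.828), against 0.013 and −0.104 in the controls, which dividing host precursors could give too.

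Haemoglobin genes fell further than resident lung genes. The median log2 fold change was −2.99 for Hbb-bs, Hbb-bt and Hba-a2 and −1.06 for 48 members of 4 resident lung lists. The difference was −1.93, with an SE of 0.34 that takes the lung genes as independent of each other. An equal dilution of all these genes by RNA of infiltrating cells would not give this difference alone. The difference is the pattern itself, though, in haemoglobin genes that were among the largest falls. It is therefore no separate test of dilution. Less whole blood in AML sections cannot be told apart from fewer red cells in the blood. The platelet list, which also covers megakaryocytes, lay 2.80 above the haemoglobin genes on the log2 scale. The SE was 0.49, taking the list's genes as independent of each other. By itself this goes against less blood of unchanged make-up only if the list's UMIs come from circulating platelets, which was not tested. Of the list's 10 members, 2 were higher past the threshold and 0 lower. The test also asked that the 2 shares co-localise across control spots with a rho above 0.2 in both, and rho was 0.178 in control 1 and 0.19996 in control 2, a narrow miss in control 2, so it was left undecided.

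Other divisions of the sections were fitted for comparison. Of the 28 divisions of 8 sections into 2 and 6, only the real one (1 of 28) gave as many genes as the 5224, the highest other giving 0, which argues against a chance division as the origin of the gene count. For lists, 17 of the 28 divisions gave at least the 15 of the real one, and the highest other gave 24, so the number of lists is no more than other divisions give. With high and low swapped within AML sections, only the real pattern (1 of 32) gave as many genes as the 5810, the highest other giving 2537. For lists, 15 of the 32 patterns gave at least 13, and the highest other gave 21, so the number of lists is again no more than other patterns give.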
